A study of Mus musculus with 15 samples.

How the data were processed

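RNA was measured on 15 Affymetrix MOE430A arrays, which carry short oligonucleotide probes grouped into probe sets, each read as the level of a transcript. The tissue was dissected from CD-1 mouse embryos on embryonic day 15, and the arrays fell into 5 groups of 3. The groups were mammary buds of wild-type (WT) embryos, mammary buds labelled PTHrP-/-, ventral skin of WT embryos, ventral skin labelled K14WT and ventral skin labelled K14-PTHrP. Per the labels' protocols, tissue of like genotype was pooled before RNA isolation, and 120 buds on average were needed for about 20 ug of total RNA. The labels do not say whether the 3 arrays of a group came from separate pools, so the p-values measure the spread between these preparations, which may be partly technical.

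Per the file headers and the submitters' processing notes, the authors normalized the arrays with GC-RMA, and the notes also name MAS5 and affy without versions. The deposited value table holds these expression levels on a log2 scale for 22690 probe sets, 64 of which are controls. The 4 lists deposited by the authors give a mean signal per group, that is, an intensity on a linear scale rounded to whole numbers, and a fold change between the 2 means. Per the file headers, the authors chose the lists with Cyber-T at a posterior probability of differential expression above 0.95 and a false discovery rate under 5%. The lists hold 639 probe sets higher and 1484 lower in buds labelled PTHrP-/- than in WT buds, and 338 higher and 215 lower in WT skin than in WT buds. The listed signals equalled the means of the linearized table values within 0.51, the allowance for rounding, for every entry of the bud groups and for 335 of 338 WT skin entries of the list of higher ones.

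Only probe sets on these lists carried a gene name here. Of 2416 annotated probe sets, 2384 had an Entrez gene ID, 2323 of these were matched to a current symbol through a RefSeq gene table of assembly GRCm38.p6, and 755 symbols were updated. That table was used for names alone, and no coordinates are given because the files name no build. The other 20309 probe sets had no name here. A planned test of all genes, with the brightest probe set standing for each gene, was therefore replaced by a test of all probe sets. The planned form was run on the 1892 named genes as an alternative. A named gene is represented by its brightest kept probe set unless another identifier is given.

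Array medians ran from 3.86 to 4.04 on the log2 scale, a range of 0.18, so no further normalization was applied. Control probe sets were left out, and a probe set was kept if it lay above its own array's median on at least 3 of the 15 arrays, which left 11690. limma 3.58.1 in R 4.3.3 fitted 5 group means with lmFit over the 15 arrays, with 10 residual degrees of freedom, followed by eBayes without a trend (prior degrees of freedom 3.09, prior SD 0.17). Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over all kept probe sets within each comparison, with a threshold of 0.05. The number of arrays limits the precision. In simulated data built on the bud comparison, the fit recovered 32.8%, 80.6% and 98.5% of probe sets changed by 0.5, 1 and 2 log2 units. For the transgenic skin comparison the recovered shares were 34.3%, 59.7% and 97.0%. Changes are given as log2 differences with the standard error (SE) of the fit, 3 arrays per group. The fit takes the spread of each probe set from all 15 arrays, so an SE is not that of the 2 groups compared alone. The median SD was 0.13 and 0.11 in the bud groups and 0.18 and 0.20 in the K14 groups. The SE can therefore be too large for the bud comparison and too small for the K14 one. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and figures.

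The comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. In the 3 main comparisons the rule named up to 8 rises and 8 falls with the largest log2 change among probe sets past the threshold whose arrays did not overlap between the groups, up to 4 members of each list by smallest adjusted p, and Pthlh and Pth1r in any case. In the other comparisons it named up to 5 rises and 5 falls. Some genes that the rule selected are not named in the text. Genes outside the rule that are named below were chosen after their values were seen. The 24 gene lists covered the Wnt, BMP and hedgehog pathways, ectodysplasin and hair placode, mammary bud epithelium, mammary mesenchyme, metalloproteinases and inhibitors, extracellular matrix, epidermal differentiation, basal keratinocytes, immediate early and cAMP response, cell cycle, androgen and estrogen response, and growth factor and retinoid signalling. They also covered markers of skeletal muscle, cartilage and bone, erythroid cells, endothelium, leukocytes, nerve and Schwann cells, melanocytes, dermal fibroblasts, adipocytes and smooth muscle. The 16 lists with at least 5 named members were tested with limma's camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over 48 tests, with fry beside it. Camera compared each list with the other named genes, all of which were on lists that the authors chose on these same arrays, so counts within the lists are not independent evidence. The number of genes given for a list below counts its named members with a kept probe set, while the lists held 11 to 50 genes. The other members were unnamed here, not kept or set aside. Set-aside probe sets, described below, were left out of the list counts. They stayed in the camera tests, both in the lists and among the other named genes. In simulated data, camera called all 50 lists shifted by 0.5 log2 units and 4 of 723 unshifted ones.

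After the data were examined, 141 probe sets were set aside in an added alternative, because the WT skin values of the table contradicted the authors' lists of skin against buds. They were over 2-fold apart between WT skin and WT buds yet absent from the list in that direction, or were listed with another signal. Of these, 135 were among the kept probe sets. Further alternatives were no filter, a filter keeping the upper 40% by mean level, quantile normalization, a fit of only the groups compared, the replicate number as a block, a variance trend with robust estimation, array weights, the mean over the probe sets of a gene, a 2-fold minimum, and leaving out each array in turn. Added later were fits without the 6 K14 arrays, and without the K14-PTHrP array of lowest weight in comparisons that did not involve it. A planned change of pseudocount did not apply because the values were already logarithms.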

Results

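Expression was measured in mammary buds and ventral skin of mouse embryos on embryonic day 15, in 5 groups of 3 arrays. PTHrP, encoded by Pthlh, is a secreted peptide made by the epithelium of the mammary bud, and its receptor Pth1r lies on the mesenchyme around it. The design sets buds labelled PTHrP-/- and ventral skin against WT buds, and skin labelled K14-PTHrP, in which a keratin 14 promoter drives PTHrP in the basal epidermis, against skin labelled K14WT. Arrays correlated at r = 0.986 to 0.998 within groups and 0.978 to 0.996 between groups, across probe sets. The median SD within a group ran from 0.11 log2 units in buds labelled PTHrP-/- to 0.20 in skin labelled K14-PTHrP.

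Pthlh, measured by a single probe set, was at a log2 level of 5.43 ± 0.51 (SD, n = 3) in WT buds and 6.40 ± 0.37 in buds labelled PTHrP-/-. The difference of 0.97 ± 0.24 (SE) did not pass the test (adjusted p = 0.211), although each of the 3 arrays labelled PTHrP-/- lay above each WT array. Chance gives a lack of overlap, in either direction, in 10% of such comparisons. In the authors' deposited table the gene stands among those higher in buds labelled PTHrP-/-, at 1.93-fold, with signals of 45 and 86. Skin held less, with 3.55 ± 0.24 in WT skin, 4.16 ± 0.26 in K14WT skin and 3.54 ± 0.13 in skin labelled K14-PTHrP. The levels in WT skin and in skin labelled K14-PTHrP lay below the median of each of those arrays, so the sizes of differences from them are not exact. The difference between the K14 groups, -0.61 ± 0.24, did not pass either (adjusted p = 0.368). The place of this probe set relative to the deleted part of the gene, and to the transgene, is not given in the sources used here, so it checks neither label. The direction of every bud difference below rests on the label. Pth1r was at 8.44 ± 0.37 in WT buds and 8.69 ± 0.07 in buds labelled PTHrP-/-, a difference of 0.25 ± 0.30 (adjusted p = 0.700).

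**Figure D1:**
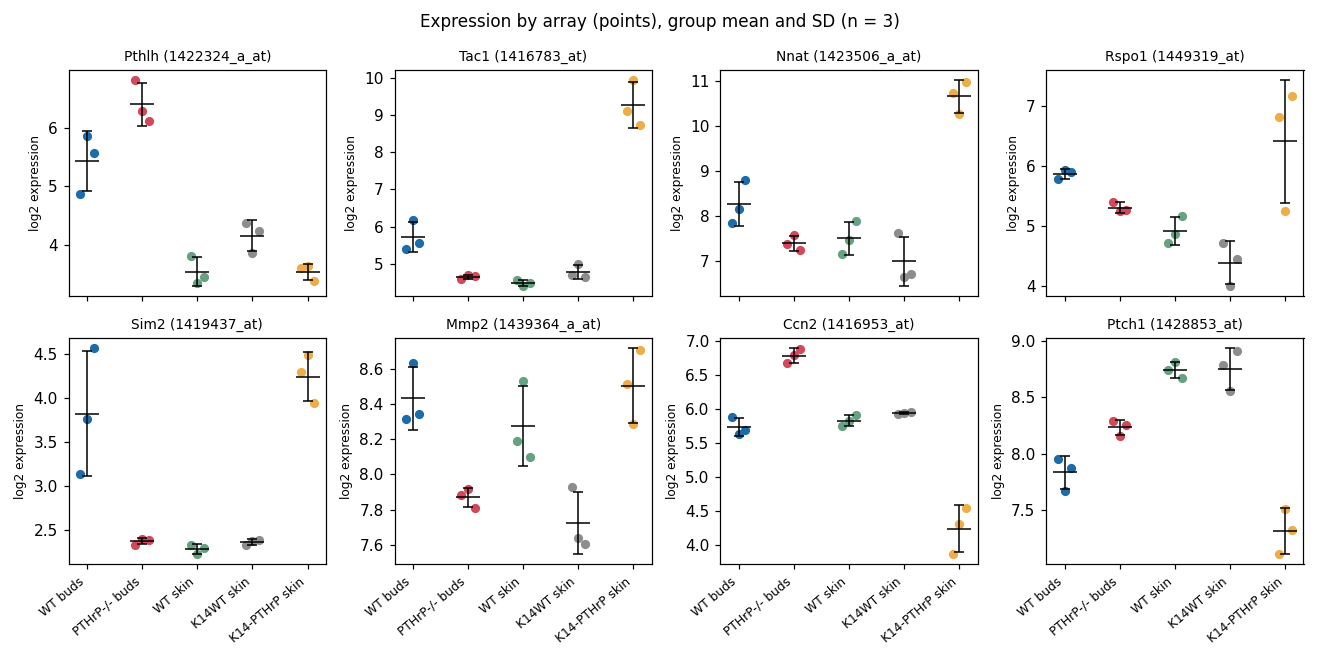
Log2 expression of 8 genes on each of the 15 arrays (points), with the group mean and SD (n = 3) as lines, for the 5 groups on the x axis. Pthlh was higher in buds than in skin and was not lower in buds labelled PTHrP-/-, and Tac1 and Nnat stood highest in skin labelled K14-PTHrP.

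The first comparison asked which transcripts differ in buds labelled PTHrP-/-. Fgfr1op2 rose 2.78-fold (log2 change 1.48 ± 0.15 SE, n = 3 per group, adjusted p = 0.00216), and Ccn2, a matricellular growth factor, rose 2.07-fold (1.05 ± 0.14, adjusted p = 0.0203). Golt1b, a protein of Golgi transport, was 3.43-fold lower (-1.78 ± 0.23, adjusted p = 0.0152). Pdlim1, an adaptor of the actin cytoskeleton, was 1.41-fold lower (-0.50 ± 0.08, adjusted p = 0.0488). These 4 of 11690 probe sets passed, each with no overlap between the groups' arrays, and 1647 had an unadjusted p under 0.05. Pdlim1 no longer passed without the set-aside probe sets (adjusted p = 0.0515, at most 0.337 over its alternatives). Only Fgfr1op2 passed when WT bud replicate 2 or 3, or replicate 1 or 2 of the buds labelled PTHrP-/-, was left out (1 call each), 6 passed without WT bud replicate 1 or replicate 3 of the buds labelled PTHrP-/-, and a fit of the 2 bud groups alone called 97 probe sets, 33 higher and 64 lower.

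No bud difference in the fixed lists passed the test, although some were several SE in size, and the SE came from all 15 arrays. The BMP target Id1 was at -0.69 ± 0.12 (adjusted p = 0.118), the immediate early gene Egr1 at -0.95 ± 0.27 (adjusted p = 0.228) and the metalloproteinase Mmp2 at -0.56 ± 0.15 (adjusted p = 0.212). The simple epithelial keratins Krt8, Krt18 and Krt19 were at -0.67 ± 0.16, -0.60 ± 0.18 and -0.64 ± 0.23 (lowest adjusted p = 0.209). No member of any of the 24 lists passed over all probe sets. Adjusted over the list alone, 5 of 6 immediate early genes, 3 of 6 metalloproteinases and inhibitors, 3 of 10 bud epithelium genes and 2 of 6 BMP genes were lower. By the same count 2 bud epithelium genes, 1 of 6 Wnt genes, 1 of 6 metalloproteinases and inhibitors, 1 of 5 mesenchyme genes and 1 of 2 melanocyte genes were higher. The hedgehog receptor Ptch1 (0.40 ± 0.12) and the cartilage collagen Col9a1 (1.08 ± 0.35), each the only member named and kept, were higher in this count. Col9a1 in WT buds and Egr1 in buds labelled PTHrP-/- lay below the median of each array, so their sizes are not exact. Wnt4 (-0.44 ± 0.19), the only hormone response gene named and kept, was lower. So was 1 member each of the mesenchyme, matrix (18 counted), basal keratinocyte (6), melanocyte and smooth muscle (2) lists. No member passed even so among 15 skeletal muscle, 11 growth factor, 11 dermal fibroblast, 9 epidermal differentiation, 9 cell cycle, 7 endothelial, 6 leukocyte, 6 adipocyte, 4 erythroid and 3 hair placode genes, and no nerve or Schwann cell gene was named. All 15 muscle genes, with a median of -0.51, were on the authors' list of lower ones, and these lists were chosen on the same arrays. No list passed camera in buds (lowest adjusted p = 0.183). Camera gave a direction relative to the other named genes, so the Wnt, mesenchyme, metalloproteinase, matrix, cell cycle, growth factor, endothelial and leukocyte lists were marked up although their medians lay below 0.

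The authors' own lists of the bud comparison were far longer. Of their probe sets higher in buds labelled PTHrP-/-, 525 were kept and all 525 had that direction in the fit, with a median of 0.43, and 2 passed the threshold. Of those listed as lower, 1407 were kept, all 1407 had that direction, with a median of -0.42, and 2 passed. The listed signals come from these same arrays, so the shared direction was all but fixed beforehand and is no independent evidence. At an unadjusted p under 0.05 the counts were 305 and 896. Probe sets ending in x_at, whose probes can bind several transcripts, made up 28.0% of the first list and 5.83% of the other, against 9.30% of all kept ones. Probe sets of 56 genes were on both lists.

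The next comparison set WT ventral skin against WT buds. In skin, Cpxm2, a carboxypeptidase-like secreted protein, was 3.80-fold higher (log2 change 1.93 ± 0.22 SE, n = 3 per group, adjusted p = 0.0034), and the adhesion molecule Vcam1 was 2.66-fold higher (1.41 ± 0.20, adjusted p = 0.0172). The protease Htra1 (1.27 ± 0.20), the Wnt inhibitor Wif1 (1.23 ± 0.18), the matrix proteoglycan Aspn (1.12 ± 0.17 at 1 of its probe sets, the other at 1.54 ± 0.48 with adjusted p = 0.204) and the hedgehog receptor Ptch1 (0.91 ± 0.12) also rose. Lower in skin were Rtn4, a shaper of the endoplasmic reticulum (-2.79 ± 0.47, adjusted p = 0.0302), Pthlh (-1.88 ± 0.24, adjusted p = 0.0115), and the transcription factors Sim2 (-1.54 ± 0.25) and Myb (-0.88 ± 0.15). The hemidesmosomal collagen Col17a1 (-0.58 ± 0.09, adjusted p = 0.0288) was lower as well. These adjusted p-values come from 11555 probe sets with the set-aside ones left out, in which 11 were higher and 6 lower. Over all 11690, 110 were higher and 104 lower, but 129 of those 214 were set-aside probe sets, and their very small p-values loosened the adjustment for the rest. All 214 had no overlap between the groups' arrays. Sim2 did not pass in a fit of the 2 groups alone (adjusted p = 0.0567). Pthlh and Sim2 in WT skin lay below the array medians, so their sizes are not exact. K14WT skin did not share the differences of Rtn4 and Cpxm2. Rtn4 read 7.74 to 8.46 in WT buds, 5.31 to 5.46 in WT skin and 8.53 to 9.26 in K14WT skin. Cpxm2 read 5.0 to 5.2, 6.9 to 7.4 and 4.7 to 5.7 in that order. For Vcam1, Htra1, Wif1, Ptch1, Pthlh, Sim2 and Col17a1, every K14WT array lay on the WT skin side of every WT bud array. The probe set for 18S ribosomal RNA read 6.90 to 7.63 in WT skin, 8.62 to 9.10 in WT buds and 9.22 to 9.74 in buds labelled PTHrP-/-, without overlap, so a difference in RNA composition or quality between these groups is not excluded.

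**Figure D2:**
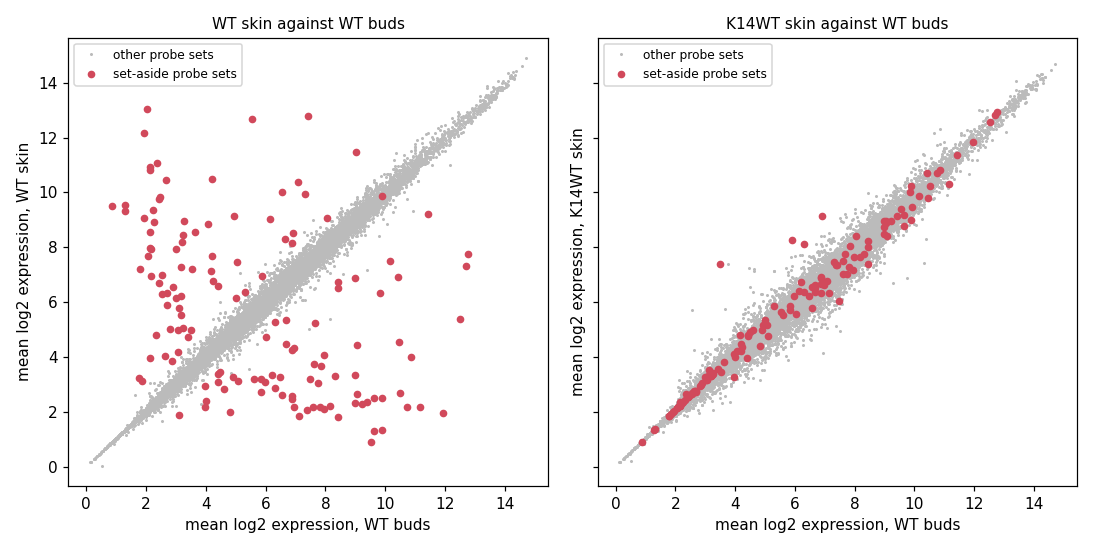
Mean log2 expression of each probe set in WT skin (left) and K14WT skin (right), y axes, against WT buds, x axes, with the 141 set-aside probe sets as large points. The median absolute difference of those over 2-fold apart was 3.81 log2 units in WT skin and 0.15 in K14WT skin, both against WT buds.

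Some gene lists passed camera at the preset correlation in WT skin against WT buds, and none with an estimated correlation. Of 10 bud epithelium genes, Pthlh, Krt18 (-0.98 ± 0.18) and Krt8 (-0.80 ± 0.16) were lower over all 11690 probe sets and 8 were lower adjusted over the list alone. Of 11 dermal fibroblast genes, Crabp1 (1.09 ± 0.21), Pdgfrb (1.04 ± 0.24) and Prrx1 (0.71 ± 0.13) were higher, 10 over the list alone. Of 18 matrix genes, the basement membrane collagen Col4a1 (0.84 ± 0.16) was higher and Col17a1 lower, 13 and 2 over the list alone. Of 6 leukocyte genes, the macrophage complement gene C1qa (0.81 ± 0.17) was higher, 5 over the list alone. Camera passed for dermal fibroblasts (up, adjusted p = 2.6e-05), matrix (up, 0.000386), leukocytes (up, 0.00076) and bud epithelium (down, 0.00076). None passed when the correlation was estimated, with adjusted p = 0.116, 0.449, 0.271 and 0.192 with an estimated correlation. Also higher were the endothelial gene Esam (0.80 ± 0.16; 1 of 7, 3 over the list alone), the metalloproteinase Mmp14 (1.16 ± 0.22; 1 of 6, 3 over the list alone), Lpl in the adipocyte list (0.57 ± 0.11; 1 of 6, 2 over the list alone) and the replication gene Mcm3 (0.45 ± 0.09; 1 of 9, likewise over the list alone). Crabp1 and Pdgfrb were also the 2 of 11 growth factor and retinoid genes that were higher, 5 over the list alone. The Wnt and BMP lists split, with Wif1 higher and Sostdc1 (-0.63 ± 0.14) and Id1 (-0.64 ± 0.12) lower, 1 higher and 2 lower of 6 Wnt genes and 1 each of 6 BMP genes over the list alone. Adjusted over the list alone, the hair placode list, in which Sostdc1 also was the only call, had 1 higher and 2 lower of 3, mesenchyme 1 and 2 of 5, and basal keratinocytes 0 and 2 of 6, with Col17a1 in the last. By that count Col9a1, Ptch1 and 1 of 2 melanocyte genes were higher, and no epidermal, immediate early, hormone response, muscle, erythroid or smooth muscle gene passed. Every named member is on a list the authors chose on these arrays. Except for Pthlh, Col17a1, Wif1 and Ptch1, the calls of the list members named here did not pass with the set-aside probe sets left out (adjusted p from 0.0581 for Krt18 to 0.116 for Pdgfrb), and all of these but Krt18 also failed without at least 1 array (adjusted p up to 0.233 for Pdgfrb). For the adipocyte list camera's direction was up with a median of -0.02 and a mean of 0.17 over 7 members. These include the set-aside Car3, and the 6 counted members had a median of -0.12.

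The transgenic comparison asked what differs in ventral skin labelled K14-PTHrP against K14WT skin. Tac1, the precursor of the neuropeptide substance P, rose 22.6-fold (log2 change 4.50 ± 0.25 SE, n = 3 per group, adjusted p = 9.43e-07), and the imprinted gene Nnat rose 12.6-fold (3.66 ± 0.30, adjusted p = 4.16e-05). Fxyd6 (1.89 ± 0.16), Sim2 (1.89 ± 0.25), Cpxm2 (1.97 ± 0.22), the RNA-binding protein Pcbp4 (2.13 ± 0.43), the Wnt agonist Rspo1 (2.03 ± 0.36) and the chromatin protein Hmga2 (1.58 ± 0.30) also rose. The glyoxalase Glo1 (-1.73 ± 0.15), Ccn2 (-1.70 ± 0.14), the peptidase Mme (-1.71 ± 0.27), Ptch1 (-1.44 ± 0.12), Egfl6 (-1.29 ± 0.26), Vcam1 (-1.25 ± 0.20), Penk (-0.87 ± 0.13) and the transcript AY036118 (-1.80 ± 0.37) fell. Sim2 and Fxyd6 lay below the median of each K14WT array, so their sizes are not exact. For Cpxm2, Pcbp4 and AY036118 the K14WT arrays stood apart from WT skin, while the K14-PTHrP arrays lay near it. Cpxm2 read 6.9 to 7.4 in WT skin, 4.7 to 5.7 in K14WT skin and 7.1 to 7.4 in skin labelled K14-PTHrP. In that order, Pcbp4 read 6.2 to 6.9, 3.8 to 5.4 and 5.9 to 7.5. AY036118 read 9.94 to 10.15, 11.21 to 12.83 and 10.07 to 10.86. So these differences are not shown to come from the K14-PTHrP side. In all, 60 probe sets were higher and 23 lower, each without overlap between the groups' arrays, and 1382 had an unadjusted p under 0.05. In a fit of these 2 groups alone 6 were higher and 1 lower, and of the genes just named Tac1, Nnat, Fxyd6, Sim2 and Glo1 still passed. The count became 210 without K14WT replicate 1, 53 without K14WT replicate 2, 48 without K14WT replicate 3 and 175 without K14-PTHrP replicate 2, and Pcbp4, Rspo1, Hmga2, AY036118 and Egfl6 each failed without at least 1 array (highest adjusted p = 0.191, 0.105, 0.138, 0.215 and 0.191), as did Vcam1 without K14WT replicate 3 (0.0506).

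Of 5 mesenchyme genes, the matrix proteoglycan Vcan (1.43 ± 0.22, adjusted p = 0.00724) and Mmp2 (0.78 ± 0.15, adjusted p = 0.0281) rose in skin labelled K14-PTHrP, 3 over the list alone, and the list median was 0.78. Camera passed for this list alone (up, adjusted p = 0.00373), and had adjusted p = 0.192 with an estimated correlation. Mmp2 read 8.10 to 8.53 in WT skin, 7.60 to 7.93 in K14WT skin and 8.29 to 8.71 in skin labelled K14-PTHrP. Part of the Mmp2 difference may therefore lie on the K14WT side. Of 6 Wnt genes, Rspo1 and the Wnt and BMP antagonist Sostdc1 (0.83 ± 0.14) were higher, and Wif1 was at -0.83 ± 0.18 (adjusted p = 0.0643), 2 higher and 1 lower over the list alone. Of 6 BMP genes, Id1 rose (0.69 ± 0.12, adjusted p = 0.0216), and the list had 1 higher and 1 lower, the same over the list alone. Of 11 growth factor genes 1 was higher, with 4 higher and 1 lower over the list alone. Higher too were Thy1 (0.98 ± 0.20) among dermal fibroblast genes (1 of 11, with 1 and 1), Lpl (0.57 ± 0.11) among adipocyte genes (1 of 6, with 2) and Col17a1 (0.57 ± 0.09), which is in the matrix list (1 of 18, with 1) and the basal keratinocyte list (1 of 6, with 2). Sostdc1 and Mmp2 were also the only calls among 3 hair placode genes (2 higher over the list alone) and 6 metalloproteinases and inhibitors (2 higher and 1 lower). No bud epithelium gene of 10 passed (2 higher and 2 lower over the list alone), the transcription factor Elf5 being at -1.53 ± 0.41 (adjusted p = 0.160). Of the rest, Ptch1 was the only hedgehog gene named and kept. Over the list alone, Col9a1 was lower and 1 endothelial and 1 melanocyte gene higher. None of the epidermal, immediate early, cell cycle, hormone response, muscle, erythroid, leukocyte or smooth muscle genes passed. For the matrix list camera's direction was down with a median of -0.02 and a mean of 0.03. Without at least 1 array the calls of Mmp2, Sostdc1, Id1, Thy1 and Lpl were lost (highest adjusted p = 0.135, 0.0654, 0.115, 0.215 and 0.157), and in a fit of the 2 groups alone so were those of Vcan and Col17a1 (0.250 and 0.295).

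**Figure D3:**
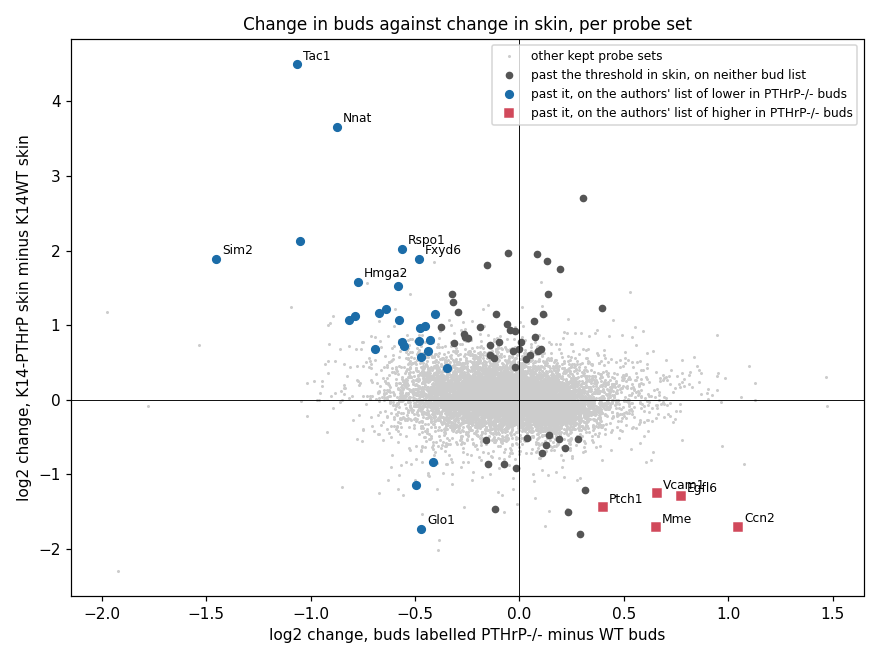
Log2 change of each kept probe set in skin labelled K14-PTHrP against K14WT skin (y axis) and in buds labelled PTHrP-/- against WT buds (x axis), with probe sets past the threshold in skin as large points. Of the 60 higher in skin, 24 were on the authors' list of lower ones in buds labelled PTHrP-/- and 0 on the list of higher ones.

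The design also asks which transcripts were shared between comparisons. In the fit over all 11690 probe sets, with set-aside ones left out of the counts, Pdlim1 alone was lower both in buds labelled PTHrP-/- and in WT skin, against 0.00658 from independent lists and 0 in each of 100 simulations of unchanged groups against the same WT buds. With nothing changed few probe sets pass the adjusted threshold, so the simulated 0 says little about this count. In the fit without set-aside probe sets this count was 0, since Pdlim1 did not pass in buds (adjusted p = 0.0515). Ccn2 alone was higher in buds labelled PTHrP-/- and lower in skin labelled K14-PTHrP, against 0.00398 from independent lists, and this held in both fits. None was lower in those buds and higher in that skin, and none met all 3 conditions. At an unadjusted p under 0.05, 145 were lower in those buds and higher in that skin (76.6 from independent lists) and 50 were the reverse (26.1). With unadjusted p-values, 251 were lower in both buds labelled PTHrP-/- and WT skin, against 50.5 from independent lists and a mean of 69.5 (50 to 90) in the simulations. For higher in both, the count was 109, against 25.4 and 70.1 (50 to 94). The simulated groups were unchanged, so their lists were not of the real length (1105 and 528 lower, 527 and 556 higher), and longer lists overlap more. Both comparisons use the 3 WT bud arrays, which cannot be divided into 2 sets of at least 2. How much of the overlap comes from these arrays therefore cannot be told. The log2 changes of the 2 comparisons correlated at 0.475 over probe sets, inside the simulated range (mean 0.498, 0.454 to 0.53). Their covariance was 0.0285, above the simulated range (mean 0.0204, 0.018 to 0.023). Between the bud and transgenic comparisons, which share no array, the correlation over probe sets was -0.163, outside the simulated range (mean 0.00195, -0.0432 to 0.0821). The simulated probe sets were drawn independently, whereas real probe sets are not independent replicates, so this range may be too narrow.

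Some genes stood in WT skin against WT buds opposite to their change in skin labelled K14-PTHrP. Sim2 and Col17a1 were lower in WT skin and higher in skin labelled K14-PTHrP, and Ptch1 and Vcam1 were the reverse. In contrast, Cpxm2 was higher in both, although K14WT skin (4.7 to 5.7) lay below WT skin (6.9 to 7.4) for this gene. In the fit without set-aside probe sets, 2 were lower in WT skin and higher in skin labelled K14-PTHrP, against 0.0317 from independent lists, 4 were the reverse, against 0.0219, 1 was higher in both, against 0.0581, and 0 were lower in both. In the fit over all probe sets, whose adjustment was loosened, the counts were 7 and 6 in opposite directions, 2 higher in both and 1 lower in both. Tac1 (-1.23 ± 0.25) and Egfl6 (1.41 ± 0.26) in WT skin passed only there (adjusted p = 0.0802 and 0.0581 otherwise). With unadjusted p-values the opposite directions had 46 against 36.6 and 42 against 27.5 from independent lists, and 79 were higher in both against 38.5, and 37 lower in both against 26.1.

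K14WT skin and WT skin, both labelled as wild-type skin, served as a control comparison. In K14WT skin Rtn4 was higher (log2 change 3.46 ± 0.47 SE, n = 3 per group, adjusted p = 0.00045), and Laptm4a (2.86 ± 0.63), AY036118 (2.15 ± 0.37), Hnrnpab (2.01 ± 0.37 at its brightest listed probe set, -0.21 and -0.14 at the others) and the stress gene Ddit4 (1.83 ± 0.36) rose too. The cell surface protein Bcam, below the array medians on K14WT replicates 2 and 3, was lower (-2.81 ± 0.50, adjusted p = 0.00471), as were Tmem14c (-2.36 ± 0.45), the chromatin remodeller Smarca4 (-2.30 ± 0.37), Pcbp4 (-2.18 ± 0.43) and the endothelial receptor partner Ramp2 (-2.04 ± 0.38). Pth1r was also lower (-1.29 ± 0.30, adjusted p = 0.0213). Of 861 probe sets past the threshold, 859 without overlap, 162 were higher and 699 lower, and quantile normalization moved this split to 251 and 436. Without the set-aside probe sets 72 were higher and 531 lower. The count was 460, 383 and 543 without WT skin replicate 1, 2 or 3, 467 and 398 without K14WT replicate 2 or 3, and 1874 without K14-PTHrP replicate 3, and Pth1r did not pass without WT skin replicate 2 or 3 or K14WT replicate 2 or 3 (adjusted p up to 0.0818), nor Laptm4a without WT skin replicate 1 (0.0627), and Ramp2 did not pass in a fit of the 2 groups alone (0.0523).

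Buds labelled PTHrP-/- were also set against WT skin. Pthlh, which lay below the array medians in WT skin, was higher in these buds (log2 change 2.85 ± 0.24 SE, n = 3 per group, adjusted p = 0.000284), and Zfp207 (1.31 ± 0.18) and Fgfr1op2 (1.24 ± 0.15) rose with it. The lipoprotein gene Apoe was lower (-2.15 ± 0.25, adjusted p = 0.00291), and so were the smooth muscle light chain Myl9 (-1.99 ± 0.34), Cpxm2 (-1.98 ± 0.22), Golt1b (-1.51 ± 0.23) and the matricellular protein Thbs2 (-1.40 ± 0.26). The p-values are those without the set-aside probe sets, where 9 were higher and 25 lower; over all 11690 the counts were 84 and 138, of which 129 were set aside. Apoe and Myl9 lay below the array medians on replicates 1 and 2 of these buds, so their sizes are not exact. Rtn4 (2.44 ± 0.47) and Sh3d19 (0.98 ± 0.22) passed only over all 11690 (adjusted p = 0.0521 and 0.0965 otherwise). For Cpxm2, Rtn4 and Sh3d19, K14WT skin did not lie with WT skin. Myl9 did not pass in a fit of the 2 groups alone (adjusted p = 0.0684), nor Thbs2 without replicate 2 of these buds or WT skin replicate 1 or 2 (up to 0.0585).

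Last, the difference WT buds minus buds labelled PTHrP-/- was compared with the difference skin labelled K14-PTHrP minus K14WT skin. It differed for 20 probe sets, 4 with the bud value higher and 16 with the skin value higher, and 1077 had an unadjusted p under 0.05. Tac1 stood at 1.07 in buds, which did not pass there, and 4.50 in skin (difference -3.43 ± 0.36 SE, adjusted p = 0.00114), and Nnat by 0.88 and 3.66 (-2.78 ± 0.42, adjusted p = 0.0194). Glo1 stood at 0.47 in buds and -1.73 in skin (2.20 ± 0.21, adjusted p = 0.000489). K14WT skin (10.61 to 10.86) lay above WT skin (9.39 to 10.07) for Glo1, so part of its skin value may lie on the K14WT side. Ptch1 was at -0.40 in buds and -1.44 in skin (1.04 ± 0.17, adjusted p = 0.0351). Only Tac1 and Glo1 of the 9 named genes passed in every alternative, the bud differences of these 4 genes did not pass on their own, and the bud terms rest on the label. The count was 8, 10 and 12 without WT bud replicate 1, 2 or 3, 9, 7 and 12 without replicate 1, 2 or 3 of the buds labelled PTHrP-/-, 10 and 9 without K14WT replicate 2 or 3, and 11 without K14-PTHrP replicate 1.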

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

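The results gathered here are the 9 named genes for which the difference between the 2 bud groups and the difference between the 2 K14 skin groups were not the same size or sign, with WT minus labelled PTHrP-/- taken in buds and labelled K14-PTHrP minus K14WT taken in skin. The comparison and its split test were fixed before the data were examined, and no test was added for it later. Tac1 (1.07 in buds, 4.50 in skin, difference -3.43, adjusted p = 0.00114) and Nnat (0.88 and 3.66, -2.78, adjusted p = 0.0194) differed more in skin, and their bud differences did not pass on their own (adjusted p = 0.209 and 0.256). Fxyd6 (0.48 and 1.89, -1.41, adjusted p = 0.0237) and Cpxm2 (0.05 and 1.97, -1.92, adjusted p = 0.0262) also passed in skin and not in buds. For Cpxm2 the K14WT arrays lay below WT skin, and the K14-PTHrP arrays did not. Glo1 passed in skin and not in buds (0.47 and -1.73, difference 2.20, adjusted p = 0.000489). Ptch1 did likewise (-0.40 and -1.44, difference 1.04, adjusted p = 0.0351). For Glo1 the K14WT arrays lay above WT skin, and the K14-PTHrP arrays lay below it. Golt1b (1.78 and -0.09, difference 1.87, adjusted p = 0.0369) and Fgfr1op2 (-1.48 and -0.09, difference -1.39, adjusted p = 0.0194) passed in buds and not in skin. Hacd3, at 0.42 in buds and -0.29 in skin, passed in neither (difference 0.71, adjusted p = 0.0448).

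Of 100 splits of the 12 arrays drawn over the labels, 11 gave as many calls as the real 20, the real split among them, and the highest other gave 119. A chance arrangement of the arrays was therefore not excluded for this count. A split that calls several times the real number points to structure among the samples beyond their labels.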

How the results depend on the processing

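No named gene and no list changed sign while past the threshold under any alternative. Of 89 calls of named genes, counted gene by comparison, 31 passed in every alternative. The cause of a shift was not tested unless the construction of the alternative shows it. Fits of only the groups compared take the spread from those groups. The median SD was lower in the bud groups (0.13 and 0.11) than in the K14 groups (0.18 and 0.20).

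For buds labelled PTHrP-/- against WT buds (4 calls as planned), a fit of only the groups compared gave 97, the same with a variance trend 173, array weights 234, and leaving out 1 array 1 to 6. The estimation of array weights stopped before its convergence tolerance, so its counts here and below are given as they came out. For WT skin against WT buds (214), the stricter filter gave 134, array weights 581, leaving out set-aside probe sets 17, leaving out the 6 K14 arrays 325, and the brightest probe set of each named gene, which tests fewer, 131.

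For skin labelled K14-PTHrP against K14WT skin (83), only the groups compared gave 7, with a variance trend 6, array weights 1352, the mean over the probe sets of a gene 46, the 2-fold minimum 40, the brightest probe set 44, and leaving out 1 array 48 to 210. For K14WT skin against WT skin (861), array weights gave 4034, the mean per gene 338, the 2-fold minimum 315, the brightest probe set 327, and leaving out 1 array 383 to 1874. For buds labelled PTHrP-/- against WT skin (222), array weights gave 667, leaving out set-aside probe sets 34, leaving out the K14 arrays 380, and the brightest probe set 136. The 2-fold minimum and the tests of named genes alone can only call from smaller sets, which accounts for part of their lower counts.

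For the bud difference minus the skin difference (20), the stricter filter gave 7, only the groups compared 13, with a variance trend 11, array weights 206, the mean per gene 8, the brightest probe set 8, and leaving out 1 array 7 to 28. The replicate number as a block gave 10. Across the groups, the replicates' deviations from their group means correlated at -0.02, -0.05 and 0.26 in the bud comparison and 0.31, 0.18 and -0.14 in the transgenic one, over probe sets, so the replicate numbers do not pair the arrays, and the block used up degrees of freedom.

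The overlap of lower in buds labelled PTHrP-/- and lower in WT skin (1) became 0 with the stricter filter, quantile normalization, the block, a variance trend, the 2-fold minimum, without set-aside probe sets and without the K14 arrays. It was 11 with only the groups compared, 15 with a variance trend added, 48 with array weights, and 0 to 2 leaving out 1 array. The overlap of lower in those buds and higher in skin labelled K14-PTHrP (0) was 37 with array weights, 1 each with the mean per gene, the brightest probe set, and only the groups compared with a trend, and 0 to 1 leaving out 1 array. The overlap of all 3 conditions (0) was 10 with array weights, 1 in the same 3 alternatives, and 0 to 1 leaving out 1 array.

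The list tests that passed numbered 5 as planned and 0 with an estimated correlation, and 5 to 8 in the fits leaving out 1 array, where lists beyond the planned 5 also passed. Of the authors' list of higher ones in buds labelled PTHrP-/- (2 past the threshold), 33 passed with only the groups compared and 57 with a trend. Of their list of lower ones (2), 64 and 116 did, and 1 with the block, with a trend in the full fit, and without set-aside probe sets. Of their list of higher ones in WT skin (40), 63 passed with only the groups compared and a trend, and 10 without set-aside probe sets. Of those lower in WT skin (36), 5 passed without set-aside probe sets.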

Other observations

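In list tests added after the main results were seen, some lists passed camera at the preset correlation for buds labelled PTHrP-/- against WT skin, and none with an estimated correlation. Bud epithelium genes leaned higher in these buds (1 of 10 past the threshold, Pthlh, median 0.30, camera adjusted p = 0.000224, and adjusted p = 0.265 with an estimated correlation). Dermal fibroblast (median -0.54, adjusted p = 0.0139, and 0.440 with an estimated correlation), matrix (-0.53, 0.0247 and 0.600) and leukocyte genes (-0.69, 0.0499 and 0.569) leaned lower. Skeletal muscle genes leaned higher in K14WT skin than in WT skin (median 0.49, adjusted p = 4.08e-05, and adjusted p = 0.600 with an estimated correlation), with 1 of 15 past the threshold and 5 over the list alone.

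Every test in the next 5 paragraphs was chosen after the result it concerns was seen, whereas the splits in the last paragraph were fixed before the data were examined. The first pattern is that 140 probe sets were over 2-fold apart between WT skin and WT buds in the deposited table yet absent from the authors' list in that direction. Values may have been exchanged between probe sets in the WT skin columns, since 49 reciprocal pairs were found there, against at most 19 in 100 shuffled tables. A difference between skin and buds is less likely, since only 5 of the 140 were also over 2-fold apart in the same direction in K14WT skin. The search was not used to restore any value.

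The next pattern is that Pthlh was not lower in buds labelled PTHrP-/- and was listed by the authors as higher. The 2 bud groups alone may carry each other's labels, and the 24 of 60 probe sets higher in skin labelled K14-PTHrP that were on the list of lower ones in those buds could argue against this only if PTHrP moved the same genes alike in buds and skin, which is not known. More non-bud tissue in the WT bud preparations might lower Pthlh there, and the median of -0.47 of the 9 other bud epithelium genes does not decide this, because 6 of them were on lists the authors chose for this comparison and the muscle genes had a median of -0.51. A transcript part outside the deletion could be what the probe set measures, and with 1 probe set of unknown place this cannot be told.

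The last pattern is the large difference between K14WT skin and WT skin. Exchanged probe sets in the WT skin columns may add to it but do not account for it, since 603 calls remained without the set-aside probe sets. Scaling between arrays could add to it too, but 456 were called after quantile normalization of the same probe sets, 383 of them among the 603 and in the same direction. More skeletal muscle in the K14WT preparations might raise muscle genes, but dilution by muscle would not lower 139 probe sets by over 2-fold. The probe set for 18S ribosomal RNA read 6.90, 7.31 and 7.63 in WT skin, 9.27, 10.8 and 10.9 in K14WT skin, 10.8, 7.50 and 8.32 in skin labelled K14-PTHrP, 9.10, 8.97 and 8.62 in WT buds and 9.22, 9.74 and 9.72 in buds labelled PTHrP-/-, so it parted WT skin from all bud arrays and the bud groups from each other too, and whether RNA composition or quality differed was not tested. The actin control at the 3' end exceeded that at the 5' end by 1.27 to 1.61 in WT skin and 1.12 to 1.34 in K14WT skin. For Gapdh these ranges were 0.66 to 0.91 and 0.46 to 0.78, so the 2 groups overlapped in both. In skin labelled K14-PTHrP replicate 3 was highest in both, with 1.08, 1.30 and 1.79 for actin and 0.30, 0.44 and 1.19 for Gapdh.

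A hypothesis is that genes lower in buds labelled PTHrP-/- may be those that PTHrP raises in skin. It was prompted by the 24 of 60 probe sets higher in skin labelled K14-PTHrP that were on the authors' list of lower ones in those buds, against 7.25 from independent lists, so this count does not test it. As wholes the 2 bud lists did not part in that skin, with a median of 0.06 and 59.6% higher for the list of lower ones and 0.04 and 57.6% for the list of higher ones. The count was 22 of 66 after quantile normalization, 4 of 6 in a fit of the 2 skin groups alone, and 10 to 40 leaving out 1 array. Relative to independent lists it was lowest, 1.96 times, without K14-PTHrP replicate 3 (12 of 51). Both sides rest on labels, and qPCR of Tac1, Nnat, Rspo1 and Mmp2 in newly genotyped buds and skin could test it.

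Another hypothesis is that skin labelled K14-PTHrP moved towards bud expression as a whole. The median change of the authors' genes lower in WT skin than in WT buds was -0.030 in that skin, so a shift of the whole list is not likely. A shift of some of its genes might still be present, since 13 of the 60 higher probe sets were on that list, against 1.03 from independent lists.

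Other splits of the same arrays were fitted for each comparison, and the 10 splits of 6 arrays are too few for a share under 0.05. The real split and the highest other called 4 and 0 probe sets for the bud comparison, 214 and 0 for WT skin against WT buds, 861 and 1 for K14WT skin against WT skin, and 222 and 0 for buds labelled PTHrP-/- against WT skin, so that 1 split, the real one, reached the real count in each. For skin labelled K14-PTHrP the real split called 83 and another 456, so 2 of 10 reached the real count. That other split set K14WT replicate 1 with K14-PTHrP replicates 1 and 3 against the rest. This points to structure among the K14 samples beyond their labels. Some epidermal differentiation genes, looked at after this split was seen, parted along it. On the side of K14WT replicate 1, Alox12b read 4.4 to 5.4 and Calml3 7.2 to 7.9. On the other side they read 7.1 to 7.3 and 9.3 to 9.5. Lor and Krt1 parted likewise, whereas Krt2, Sfn, Ovol1 and Cldn4 overlapped between the sides. The globin gene Hbb-y parted the other way, at 12.49 to 13.33 on the side of K14WT replicate 1 and 11.08 to 11.29 on the other. The erythroid genes Hba-a1, Hbb-b1 and Alas2 overlapped. Within each K14 group, Rspo1, Hmga2 and Pcbp4 read higher on the side of K14WT replicate 1. That side holds more K14-PTHrP than K14WT arrays, so part of their rise may go with the split. What underlies the split was not tested. The K14-PTHrP replicate 3 array had the lowest array weight, 0.221. Its mean r over probe sets was 0.993 with WT buds and likewise with buds labelled PTHrP-/-, against 0.988 with its own group. For the list tests, here adjusted over the lists of 1 comparison instead of all 48 tests, 4 of 10 splits reached the real 6 in WT skin against WT buds, with 7 as the highest other, and 7 of 10 reached the real 1 in skin labelled K14-PTHrP, with 5 as the highest other.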
